A study of Homo sapiens with 6 samples.

How the data were processed

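RNA sequencing libraries from U2OS cells, a human osteosarcoma line, were compared in 2 groups of 3. The control group received a scramble short hairpin RNA (shRNA) and the other group an shRNA against E4F1. Per the labels' protocols, cells were infected for 24 h, kept under puromycin for 48 h and harvested 72 h after infection, and polyadenylated RNA was made into libraries with a KAPA HyperPrep kit. The labels describe 3 independent pools of cells. They do not say whether pools with the same number in both groups were handled together.

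The deposited files hold raw read counts per gene, 1 table per library, in the layout of STAR's gene counting. Per the submitters' processing notes, the tools were bcl2fastq 2.20 and STAR 2.5.1b and the genome build was GRCh38. The release of the gene annotation is not given in the sources used here. Each table has a count column that ignores strand and a count column for each strand. The forward-strand column held 885046 to 977742 reads in genes, against 14947085 to 16892139 in the reverse-strand column, so the latter was used. With strand used, antisense genes were counted apart. Reads of overlapping genes on the same strand, and reads that map to several places, were in separate lines of the tables and in no gene. Those lines (unmapped, multimapping, in no gene, ambiguous) held 27.1% to 31.7% of each table and stayed out of library sizes and tests. Genes with near-identical copies, such as PDPR, DGCR6L, HSPA1A, HSPA1B and the histone genes, were counted from uniquely mapped reads and their values are uncertain to that extent.

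Gene symbols, types and coordinates came from GENCODE release 29 on GRCh38. Of 58219 gene identifiers in the tables, 57881 matched this release without the version number and 55050 also with it. All coordinates are 1-based.

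Counts were tested with edgeR 4.0.16 (R 4.3.3): low counts were removed with filterByExpr by group, libraries were scaled with TMM, and groups were compared by the quasi-likelihood F-test with group as the only term, two-sided. Adjusted p-values are by the Benjamini-Hochberg method over the 15765 genes tested, and the threshold was 0.05. CPM values, read counts scaled to the reads in genes of each library, are TMM-scaled and given as mean ± SD with n = 3 libraries per group. Log2 fold changes are E4F1 shRNA over control shRNA, with the standard error (SE) of the fit. The edgeR p-values measure the spread between the 3 pools of a group. For a single value, 3 libraries against 3 allow no exact permutation p below 0.1.

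Gene lists were fixed before the data were examined, as 32 lists with 908 entries, 907 of which were found in the annotation. They came from general knowledge of the pathways. The list of E4F1 targets names genes given in earlier work, and the study behind these samples may have named some of them, so that list may not be independent evidence. Lists with at least 5 genes tested, 30 in all, were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, two-sided, and adjusted over the 30 lists. Camera compares a list with the other genes. With the preset correlation it takes the genes of a list as nearly independent. The estimated correlation was 0.79 in the DNA replication list and 0.86 in the mitosis list. The camera p-values are therefore no measure of the spread between pools alone. Beside camera stand the numbers of members past the edgeR test over all genes and adjusted over the list alone.

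Genes were named by a rule fixed before the data were examined: E4F1, the members of the E4F1 target list, the 12 largest rises and 12 largest falls among protein-coding genes at adjusted p 0.05 with average log2 CPM of at least 3 and no overlap between groups, and up to 4 members per list with the smallest adjusted p. Some genes that this rule names are not reported here.

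Alternatives were DESeq2 1.42.0 (Wald test, and its size factors in edgeR), limma-voom, library totals as the only scaling, no or a stricter low-count filter (1 CPM in 3 libraries), the replicate number as a block, a GC-content offset, both together, leaving out each library in turn, glmTreat, camera with an estimated correlation, camera on ranks and fry. After the data had been seen, counts ignoring strand and a cell cycle score per library as a covariate were added. The score is the mean log2 CPM of the DNA replication and mitosis lists.

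A scan related heptamers in annotated 3' untranslated regions (UTRs) to the log2 fold changes of 11045 genes. It covered 8138 heptamers and left out the less frequent ones and those in nearly all UTRs. Each heptamer was fitted with the length and GC content of the UTR, and extremes were set against 100 permutations of the genes. These permutations, and Fisher's exact tests on counts of genes, measure spread over genes and not between pools.

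The steps were tested on simulated data with the means and library sizes of these libraries. Of the genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold in a simulation with 15557 genes, 54%, 70%, 94% and 100% were recovered, with 8 false calls (4.82% of the calls). Each size had 49 or 50 changed genes, none of them among the lowest expressed, and genes varied independently. The real libraries had many more changed genes and differences shared by many genes, so these rates may not hold for them. A count of 3 reads, used as the floor of detection, is 0.178 to 0.201 CPM in these libraries.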

Results

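E4F1 is a zinc finger transcription factor that also has a ubiquitin ligase activity. The design compares U2OS cells that received an shRNA against it with cells that received a scramble shRNA and asks which transcripts differ once E4F1 is depleted. Reads in genes numbered 14947085, 16284450 and 15625332 in the 3 control libraries and 16169103, 16892139 and 16159934 in the 3 E4F1 shRNA libraries. At this depth 25378 to 26188 genes had at least 1 read per library.

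E4F1 mRNA was lower in all 3 libraries that received the E4F1 shRNA. The gene (ENSG00000167967.15, GRCh38 chromosome 16, 2223566 to 2235742, plus strand) had 233, 286 and 297 reads in the control libraries and 51, 53 and 41 reads in the E4F1 shRNA libraries. Its level was 17.5 ± 1.76 CPM (SD, n = 3) in control cells and 2.95 ± 0.384 CPM (SD, n = 3) after knockdown, a 5.92-fold lower value. The log2 fold change was −2.57 (SE 0.135, edgeR adjusted p = 7.66e-10).

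Of 8 genes named in earlier work as E4F1 targets, 5 fell and none rose, both over all genes tested and adjusted over the list alone. DLAT, the acetyltransferase subunit of the pyruvate dehydrogenase complex (chromosome 11, 112024814 to 112064390), went from 123 ± 6.76 to 38.0 ± 3.76 CPM (n = 3 each), a log2 fold change of −1.70 (SE 0.07, edgeR adjusted p = 2.88e-11). TTI2, a subunit of the TTT complex that assists the assembly of PIKK kinases, went from 15.8 ± 1.37 to 6.33 ± 0.766 CPM (log2 −1.32). ELP3, the catalytic subunit of Elongator, fell by 0.67 on the log2 scale, PDPR, a regulator of pyruvate dehydrogenase phosphatase, fell by 0.49, and the checkpoint kinase gene CHEK1 fell by 0.34 (edgeR adjusted p = 0.00113). These 5 genes were lower in every E4F1 shRNA library than in every control library. The other 3 did not pass the test. Among them, the mitochondrial pyruvate carrier gene MPC1 had log2 −0.12 (SE 0.10, edgeR adjusted p = 0.379) and DLD −0.05 (SE 0.06, 0.576). The list lay below other genes in camera (adjusted p = 0.000117, and adjusted p = 0.553 with an estimated correlation).

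**Figure D1:**
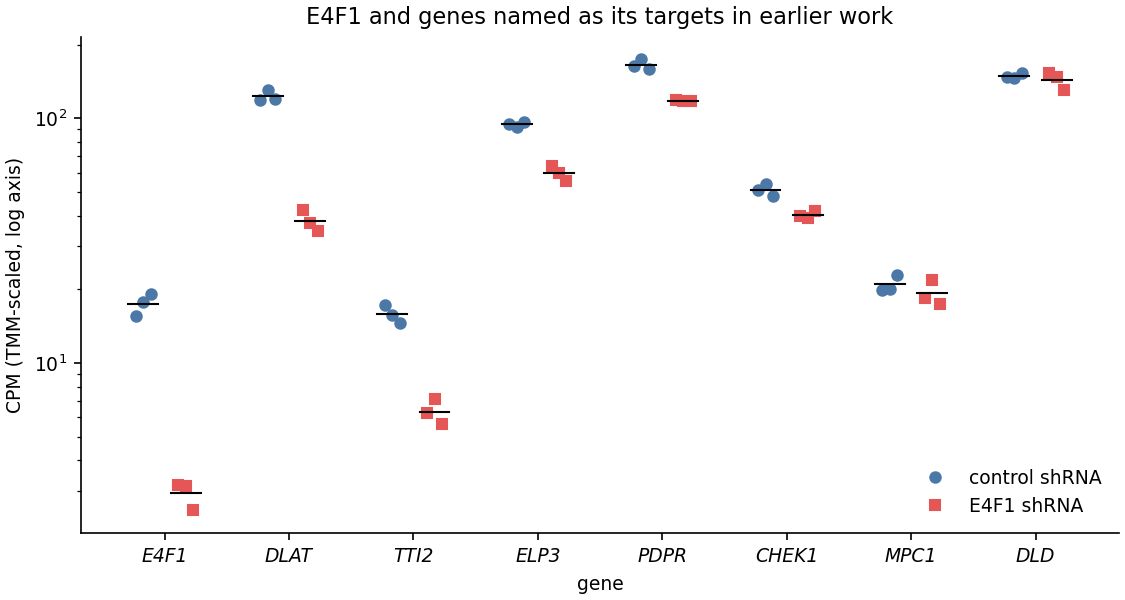
CPM on a log axis of E4F1 and 7 of the 8 genes named as its targets, with 1 point per library and a line at the group mean (3 control shRNA and 3 E4F1 shRNA libraries). E4F1, DLAT, TTI2, ELP3, PDPR and CHEK1 show no overlap between groups, while MPC1 and DLD overlap.

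The largest falls among well expressed protein-coding genes included those of DPH5, E4F1 itself and KIFBP. DPH5, a methyltransferase of diphthamide synthesis on elongation factor EEF2 (chromosome 1, 100989623 to 101026088), went from 39.3 ± 1.76 to 3.82 ± 0.829 CPM, 10.3-fold lower (log2 −3.36, SE 0.12, edgeR adjusted p = 1.83e-12, n = 3 each). KIFBP, a kinesin-binding protein gene, went from 60.9 ± 2.10 to 10.4 ± 0.853 CPM (log2 −2.55). DGCR6L (log2 −1.89), DLAT, the cardiolipin synthase gene CRLS1 (log2 −1.63), ZNHIT6 (log2 −1.57), ITFG1 (log2 −1.51), NEURL4 (log2 −1.47) and the Fanconi core complex gene FAAP100 (log2 −1.43) followed. ESM1 had the same log2 fold change as NEURL4, −1.47, but its control libraries spread widely (16.2 ± 7.57 CPM, against 5.84 ± 0.556 after knockdown), and its call was lost with the cell cycle score as a covariate.

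The largest rises among well expressed protein-coding genes were those of NDUFAF3, TCEA1 and MCU. NDUFAF3, an assembly factor of respiratory complex I, went from 5.27 ± 1.13 to 18.7 ± 1.16 CPM (log2 1.82, edgeR adjusted p = 3.01e-08, n = 3 each). TCEA1, a transcription elongation factor gene (chromosome 8, 53966552 to 54022529), went from 40.5 ± 2.22 to 142 ± 7.32 CPM (log2 1.81), and MCU, the pore subunit of the mitochondrial calcium uniporter (chromosome 10, 72692131 to 72887694), from 26.2 ± 1.05 to 85.5 ± 2.38 CPM (log2 1.71). TMEM38B, a cation channel gene of the endoplasmic reticulum, had log2 1.57, the CDP-diacylglycerol synthase gene CDS1 1.49, CDK19 1.38, the isocitrate dehydrogenase gene IDH1 1.33, DDIT4 1.33, the mitochondrial phosphoenolpyruvate carboxykinase gene PCK2 1.22, MFSD6 1.17, the complex I subunit gene NDUFS3 1.17 and USP14 1.15. The heptamer CTTATCT stood in the 3' UTR of 9 of these 12 genes, all but CDS1, DDIT4 and MFSD6.

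**Figure D2:**
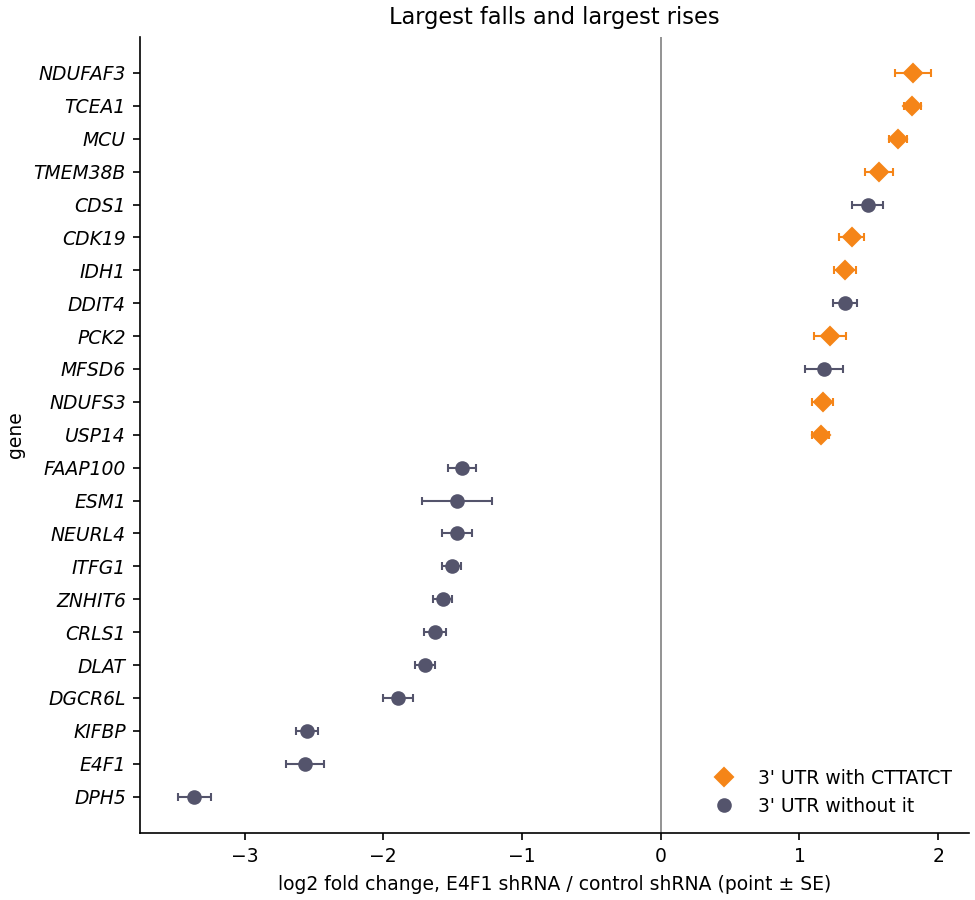
Log2 fold change (E4F1 shRNA over control shRNA, point ± SE, 3 libraries per group) of 11 of the 12 largest falls and the 12 largest rises, with genes whose 3' UTR holds CTTATCT drawn as diamonds. Values run from −3.36 for DPH5 to 1.82 for NDUFAF3, and 9 of the 12 rises are diamonds.

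Across all 1214 genes scanned with CTTATCT in the 3' UTR, a comparison made after the data had been seen, levels were higher in E4F1 shRNA cells by 0.16 on the log2 scale (SE 0.0086) once UTR length and GC content were fitted. Of these genes 43.7% rose, against 15.8% of genes without the heptamer, and 8.07% fell, against 17.9%. Relative to the mean of the 6 libraries, genes with the heptamer lay at −0.08, −0.057 and −0.097 in the control libraries and at 0.076, 0.083 and 0.075 in the E4F1 shRNA libraries. The lowest heptamer of the same scan was TGCTTTA, with a shift of −0.057 (SE 0.0072) over 2179 genes. That sign came only with UTR length and GC content fitted: without the fit, 25.1% of genes with TGCTTTA rose, against 17.3% of genes without it, 15.7% fell, against 17.1%, and the median log2 fold change was 0.043 with it and −0.0041 without it.

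**Figure D3:**
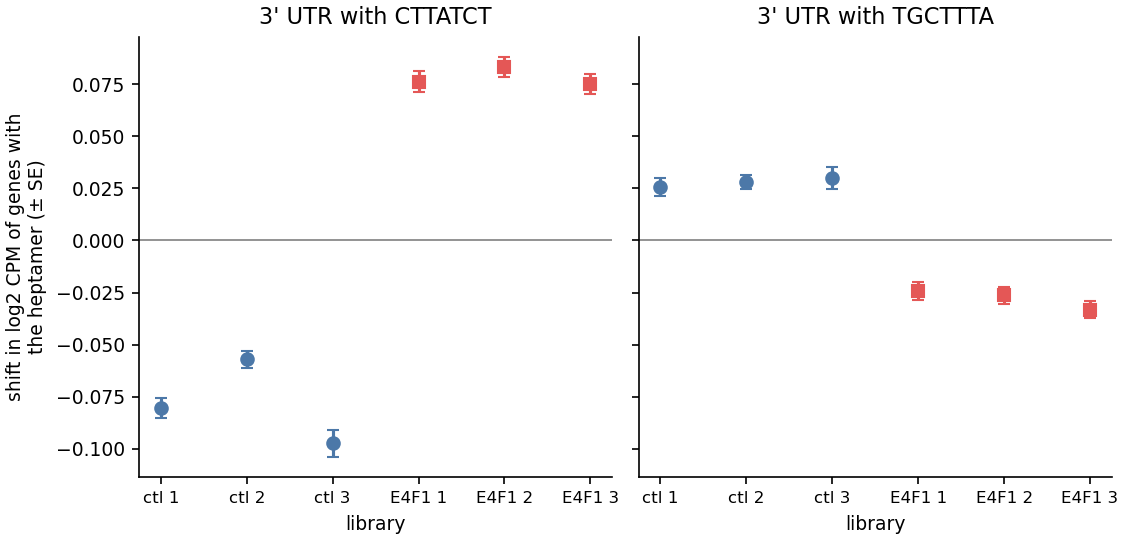
Shift in log2 CPM (± SE over genes), with UTR length and GC content fitted, of genes with CTTATCT or TGCTTTA in the 3' UTR, in each of the 6 libraries relative to their mean. CTTATCT genes lie between −0.097 and −0.057 in control libraries and between 0.075 and 0.083 in E4F1 shRNA libraries, and TGCTTTA genes lie above 0 in control and below 0 in E4F1 shRNA libraries.

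In all, 4550 of 15765 genes (28.9%) changed, 2274 up and 2276 down, most by little: the median size of the change was 0.35 on the log2 scale. Changes of at least 2-fold numbered 233, of which 74 were rises and 159 falls. All libraries of one group lay above all of the other for 6591 genes (41.8%), where chance gives 10% for 3 against 3. The count of 4550 came to 3031 without E4F1 shRNA library 2 and to 972 with the cell cycle score as a covariate, and the 233 came to 425 without control library 2. When the 2-fold size itself was tested with glmTreat, 25 genes passed, 10 up and 15 down.

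Genes of the integrated stress response, which ATF4 activates under amino acid or mitochondrial stress, rose together. Of 29 measured, 23 rose and 1 fell (24 and 1 adjusted over the list alone), with a mean log2 fold change of 0.50. DDIT4, an inhibitor of mTORC1 signalling, went from 36.4 ± 4.12 to 91.4 ± 10.3 CPM, PCK2 from 21.6 ± 4.94 to 50.3 ± 3.93 CPM, the lipoprotein receptor gene VLDLR from 31.1 ± 2.2 to 54.5 ± 1.82 CPM and the asparagine synthetase gene ASNS from 169 ± 15.9 to 269 ± 9.09 CPM (n = 3 each). The camera test gave adjusted p = 1.21e-10, and adjusted p = 0.553 with an estimated correlation. Cytosolic tRNA synthetases did not pass as a list (camera adjusted p = 0.0584), although 8 of 20 rose and none fell (8 and 1 adjusted over the list alone), among them NARS1 (log2 0.40) and AARS1 (log2 0.31). Of endoplasmic reticulum chaperones and unfolded protein response genes, 3 of 20 rose and 1 fell (3 and 0 adjusted over the list alone), with XBP1 at log2 0.34 (camera adjusted p = 0.735). Of heat shock proteins, 3 of 15 rose and 1 fell (the same numbers adjusted over the list alone), with HSPA1A at log2 0.58 (camera adjusted p = 0.349).

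Cholesterol synthesis genes fell. Of 24 measured, 15 fell and 1 rose (the same adjusted over the list alone), with a mean of −0.32 (camera adjusted p = 6.72e-06, and adjusted p = 0.593 with an estimated correlation). HMGCS1, the enzyme before HMG-CoA reductase, went from 410 ± 105 to 208 ± 2.06 CPM, FDFT1 from 191 ± 21.6 to 131 ± 5.06 CPM and SQLE from 202 ± 9.51 to 151 ± 8.04 CPM (n = 3 each). Fatty acid synthesis genes went both ways, 3 up and 6 down of 15 (3 and 7 adjusted over the list alone), with the elongase gene ELOVL5 at log2 0.62 and the fatty acid synthase gene FASN at −0.50 (camera adjusted p = 0.487).

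**Figure D4:**
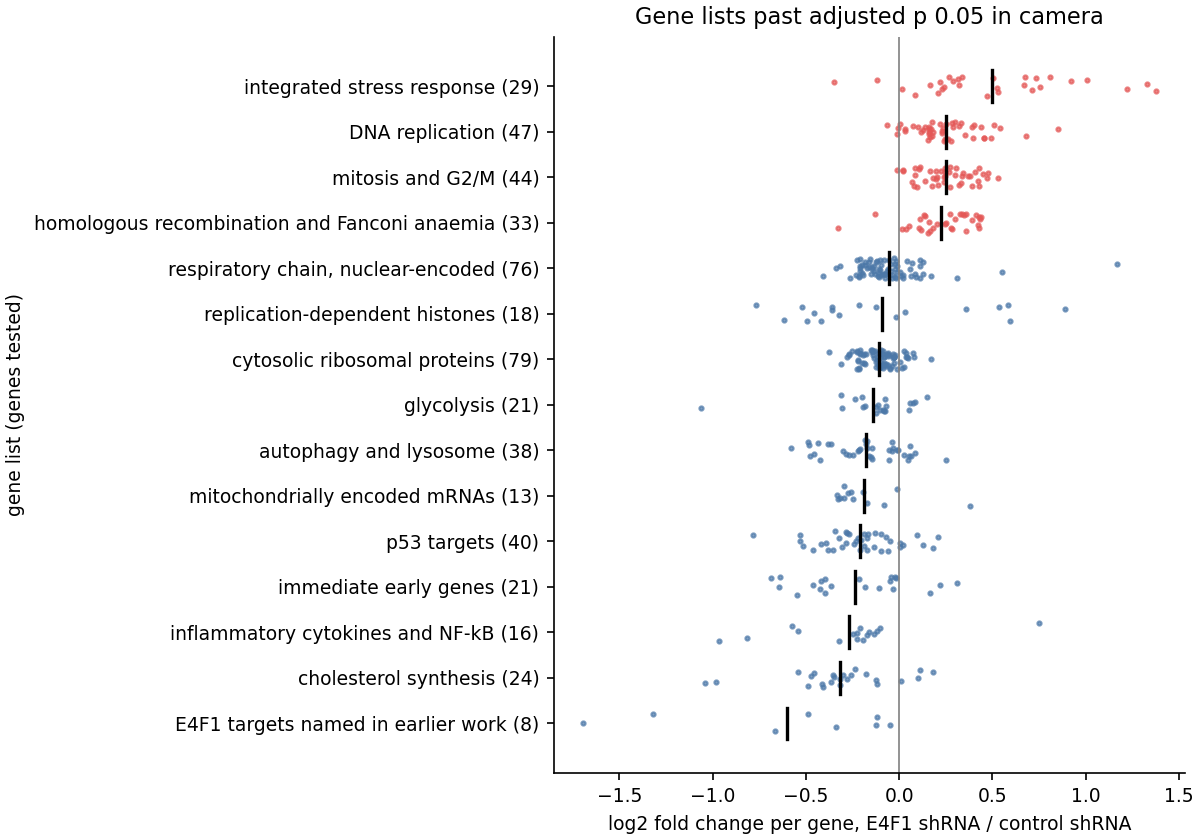
Log2 fold change (E4F1 shRNA over control shRNA) of each gene in the 15 lists past adjusted p 0.05 in camera, with a line at each list's mean and the number of genes tested in brackets. The means run from −0.60 for E4F1 targets to 0.50 for the integrated stress response.

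Genes of DNA replication, mitosis and recombination were higher in E4F1 shRNA cells. Of 47 replication genes 27 rose and none fell (33 and 0 adjusted over the list alone), with ORC6 at log2 0.68 and RFC4 at 0.85 (camera adjusted p = 1.07e-07). Of 44 genes of mitosis and G2/M, 31 rose and none fell (33 and 0), with CCNA2, the cyclin A2 gene, at 0.47 and CENPE at 0.43 (camera adjusted p = 1.07e-07). Of 33 genes of homologous recombination and the Fanconi anaemia pathway, 20 rose and 1 fell (the same adjusted over the list alone), with BRIP1 at 0.42 and BLM at 0.43 (camera adjusted p = 7.32e-06). Each of these 3 lists had adjusted p = 0.644 with an estimated correlation. Control library 2 stood apart from the other controls along this line: its mean over the mitosis list was 0.0437 on the log2 scale relative to the 6 libraries, against −0.157 and −0.271 in control libraries 1 and 3 and 0.0436 in E4F1 shRNA library 3. On the first principal component control library 2 lay at −9.85, controls 1 and 3 at −20.9 and −31.1, and the E4F1 shRNA libraries at 17.5 to 22.7.

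Targets of p53 were lower, with 21 of 40 down and 2 up (23 and 2 adjusted over the list alone) and a mean of −0.21. BTG2, an antiproliferative gene, went from 114 ± 12.1 to 66.6 ± 1.30 CPM, and SESN1 (log2 −0.53), PLK2 (log2 −0.32) and TNFRSF10B (log2 −0.42) also fell. Of autophagy and lysosome genes 18 of 38 fell and 1 rose (23 and 1 adjusted over the list alone), with the autophagy receptor gene SQSTM1 from 416 ± 43.7 to 298 ± 11.8 CPM and the kinase gene ULK1 from 24.2 ± 1.36 to 16.2 ± 1.89 CPM. The camera tests gave adjusted p = 0.000335 for p53 targets and 0.00037 for the lysosome list, each with adjusted p = 0.644 with an estimated correlation. Control library 2 was nearest to the E4F1 shRNA libraries here too, with a mean over the p53 list of −0.042, against 0.14 and 0.21 in the other controls and −0.032 in E4F1 shRNA library 3. With the cell cycle score as a covariate the mean of the p53 list was 0.016, and the recombination and lysosome lists lost their calls, as did the replication and mitosis lists, from which the score is made.

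**Figure D5:**
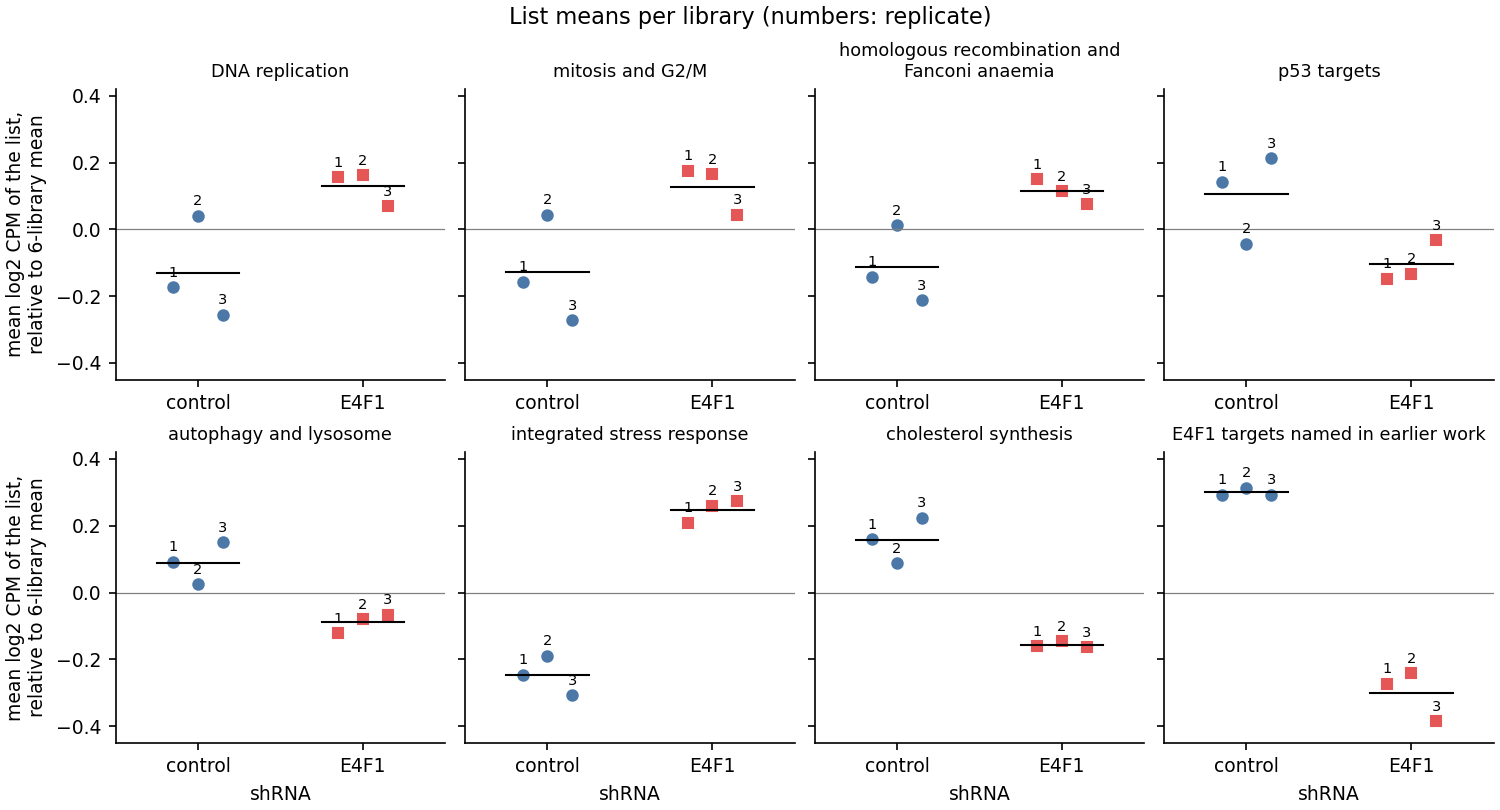
Mean log2 CPM of 8 gene lists in each library relative to the mean of the 6 libraries, with a line at the group mean and the replicate number at each point. Control library 2 lies at 0.0437 in the mitosis list, level with E4F1 shRNA library 3, and apart from all E4F1 shRNA libraries in the integrated stress response list.

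Mitochondrial and ribosomal transcripts changed by small amounts. Of 13 mitochondrially encoded mRNAs 10 fell and 1 rose (the same adjusted over the list alone), with MT-ND4 at log2 −0.33, MT-CO3 at −0.32 and MT-CO1 at −0.29 (camera adjusted p = 0.00364). Mitochondrially encoded genes took 6.16% to 6.52% of gene reads in control and 5.02% to 5.66% in E4F1 shRNA libraries. Of 76 nuclear-encoded respiratory chain genes 16 fell and 4 rose (13 and 4 adjusted over the list alone). COX4I1 had −0.41 and ATP5MC2 −0.32, while NDUFS3 (1.17) and UQCRQ (0.55) rose (camera adjusted p = 0.0292). Cytosolic ribosomal protein genes fell in 24 of 79 cases and rose in none, also adjusted over the list alone, with RPL28 at −0.28 and RPS19 at −0.27 (camera adjusted p = 4.74e-05). These 3 lists had adjusted p = 0.644 with an estimated correlation, and the respiratory chain list lost its call without control library 1 or 2 (camera adjusted p = 0.0530 and 0.0553), without E4F1 shRNA library 1 or 3 (0.0709 and 0.142) and without a low-count filter (0.0841). Mitochondrial ribosomal proteins did not move as a list, with 7 up and 5 down of 78 (4 and 4 adjusted over the list alone), a median of −0.013, a mean of −0.0082 and a test direction of up (camera adjusted p = 0.952). Their largest change was MRPL15 at −0.77.

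The pyruvate entry, Elongator and PIKK lists did not pass in camera, although each held listed E4F1 targets that fell. Of 22 genes of pyruvate dehydrogenase and pyruvate entry 4 rose and 4 fell, also adjusted over the list alone, with MPC2, the partner subunit of MPC1, from 25.3 ± 3.29 to 47.7 ± 1.19 CPM (camera adjusted p = 0.906). In this list 6 genes, MPC2 among them, held CTTATCT in the 3' UTR. The mean was −0.14 (SE 0.11 over genes) without these 6 and −0.036 with them. Of 14 genes of Elongator and wobble uridine modification 2 rose and 3 fell, also adjusted over the list alone, with CTU1 at −0.57 and ELP4 at 0.28. Their median was 0.0027 and their mean −0.08, with a test direction of down (camera adjusted p = 0.735). Of 13 genes of PIKK kinases and their assembly TTI2 fell and no other passed, also adjusted over the list alone. PRKDC had log2 0.15 (edgeR adjusted p = 0.0689) and ATM 0.12 (0.261). The list's median was 0.07 and its mean −0.06, with a test direction of up (camera adjusted p = 0.871).

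Inflammatory and growth-response transcripts were lower on average. Of 16 inflammatory cytokine and NF-kB genes 7 fell and 1 rose (the same adjusted over the list alone), with BIRC3 at log2 −0.97 and IL11 at −0.81 (camera adjusted p = 0.0169). Of 21 immediate early genes 8 fell and 2 rose (9 and 3 adjusted over the list alone), with FOSL1 at −0.65 and MYC at −0.40 (camera adjusted p = 0.0261). Both lists had adjusted p = 0.644 with an estimated correlation. The groups overlapped in the NF-kB list: relative to the mean of the 6 libraries, its genes lay at 0.21, −0.15 and 0.32 in the control libraries and at −0.21, −0.083 and −0.086 in the E4F1 shRNA libraries. The NF-kB list lost its call without control library 1 or 3 or E4F1 shRNA library 1 (camera adjusted p = 0.0794, 0.0784 and 0.0687). The immediate early list lost it with the GC-content offset (0.359) and without control library 3 or E4F1 shRNA library 1 or 2 (0.0837, 0.0704 and 0.156). Of 28 interferon response genes 3 rose and 5 fell, also adjusted over the list alone, with IFIT1 at 0.77 and SAMD9L at −0.60 (camera adjusted p = 0.683).

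Glycolysis genes fell in 6 of 21 cases and rose in none (6 and 1 adjusted over the list alone), with ALDOA at −0.24 and PKM at −0.18 (camera adjusted p = 0.0391, and adjusted p = 0.644 with an estimated correlation). The call was lost with the GC-content offset (camera adjusted p = 0.461), without a low-count filter (0.0586) and without control library 3 or E4F1 shRNA library 1 or 3 (0.117, 0.101 and 0.0859). Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, fell in 6 of 18 cases and rose in none (7 and 1 adjusted over the list alone), with H2BC4 at −0.77 and H2BC11 at −0.62 (camera adjusted p = 0.0469, and adjusted p = 0.593 with an estimated correlation). That call was lost without any of 5 libraries in turn, all but control library 3 (camera adjusted p from 0.0532 to 0.0897), with the GC-content offset (0.0527), without a low-count filter (0.0575), on ranks (0.065) and ignoring strand (0.0627). With the cell cycle score as a covariate the histone, glycolysis, NF-kB, immediate early and respiratory chain lists lost their calls.

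Hypoxia targets held 5 rises and 2 falls of 18 (6 and 2 adjusted over the list alone), with VEGFA from 47.7 ± 5.46 to 83.8 ± 0.900 CPM and NDRG1 from 126 ± 4.88 to 88.7 ± 1.28 CPM (camera adjusted p = 0.0693). NRF2 targets also went both ways, 5 up and 6 down of 22 (6 and 8 adjusted over the list alone), with the cystine transporter gene SLC7A11 at log2 0.53, GCLC at 0.46 and AKR1C3 at −0.55 (camera adjusted p = 0.526). Of 34 collagen and matrix genes 4 rose and 12 fell (5 and 14 adjusted over the list alone), with COL8A1 at 0.63 and TGFBI at −0.61 (camera adjusted p = 0.0683). Of 10 genes of the osteoblast lineage 2 rose and 2 fell (2 and 3 adjusted over the list alone), with TNFRSF11B, the osteoprotegerin gene, at 0.88 (camera adjusted p = 0.843). Their median was −0.10 and their mean −0.01, with fry pointing up.

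Markers of epithelial, blood and endothelial cells were low in all libraries, while packaging line genes summed to 275 to 311 CPM per library, from a source that was not tested. Of 6 blood cell genes tested none changed, also adjusted over the list alone (median −0.08, mean −0.06, test direction up, camera adjusted p = 0.735). Control library 2 held more reads of several blood-type genes: MPO had 3, 210 and 9 reads in the control libraries and 38, 93 and 48 in the E4F1 shRNA libraries, and LYZ had 4, 69 and 4 against 16, 26 and 24. Of 9 genes of the packaging line HEK293T 3 rose and 2 fell, also adjusted over the list alone, with SOX2 at log2 0.87 and BEX1 at −0.37 (camera adjusted p = 0.486). Too few epithelial and endothelial genes were tested for a list test. Of 4 epithelial genes 1 rose and 2 fell (2 and 2 adjusted over the list alone), with CLDN4 at −0.49 and EPCAM at 0.43. None of 3 endothelial genes changed, also adjusted over the list alone, and their median was −0.014 against a mean of 0.03.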

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

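Shares of reads outside the gene counts were compared after the data had been seen, and the counts over other splits of the samples were planned. The share of reads in no gene when counted on the opposite strand averaged 79.4% ± 0.407 in the E4F1 shRNA libraries and 77.8% ± 0.272 in the control libraries (SD, n = 3 each), with no overlap between 79.0% to 79.8% and 77.52% to 78.04%. It was singled out because it comes from a count column the comparisons did not use and lay above the level in the control samples. In the same libraries, reads that mapped to several places were 14.2% to 15.1% after E4F1 shRNA and 15.8% to 16.4% in control, and unmapped reads 1.67% to 1.69% and 1.88% to 1.98%. Genes on the opposite strand held a mean of 4.21% and 4.08%. As the shares of a library add up to the whole, the higher share in no gene mainly restates the lower multimapping and unmapped shares.

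The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Of these 10 splits, 1, the real one, gave 4550 changed genes in the edgeR test, and the highest of the other splits gave 0 (96 to 1147 genes at an unadjusted p under 0.05, against 6254 in the real split). For changes of at least 2-fold the real split, again 1 of 10, gave 233 and the highest other 0. Every other split mixes both shRNAs, so a difference between them enters the spread within its groups and lowers its calls. The low gene counts there do not tell what made the groups differ. For gene lists the real split, 1 of 10, gave 15 and the highest other 13. The splits that exchanged control library 2 for an E4F1 shRNA library gave 11 to 13 lists, which points to a structure of the samples in which control library 2 lies towards the E4F1 shRNA libraries.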

How the results depend on the processing

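Counts ignoring strand and the cell cycle score as a covariate were chosen after seeing the data, and all other alternatives were planned. E4F1 kept its direction and its call in every alternative that gave it a value (glmTreat was kept only as counts of genes, and camera and fry test lists), with −2.63 to −2.45 when each library was left out. Over the alternatives, named genes kept direction and side of the threshold in 2314 comparisons, lost the call in 138 (63 of them with the covariate), gained one in 10 and turned direction in 18. Lists did so in 441, 66, 8 and 24. DESeq2 called 3728 genes, of which 3718 were among the 4550, and limma-voom 4456, of which 4413 were. With the GC-content offset 3924 were called, 3136 of them shared, so that many calls depend on this correction. In the simulation, in which genes varied independently, 54% of the smallest changes were recovered, against 100% of the largest.

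Same-numbered libraries of the groups did not deviate together (correlations 0.007, 0.047 and 0.048), so the numbers were not used as pairs. With the replicate block 4865 genes changed, 240 by at least 2-fold, and 12 lists were called, without the respiratory chain, glycolysis and histone lists (camera adjusted p = 0.0516, 0.054 and 0.0631). With the block and the GC-content offset these were 3970, 237 and 12, without the glycolysis, immediate early and histone lists (0.444, 0.222 and 0.0637). In these deviations from the group mean, control library 2 correlated best with E4F1 shRNA library 1 (0.066), so not every sample went best with its own number. In log2 CPM itself it correlated best with E4F1 shRNA library 2 (0.9904, against 0.9899 with library 1).

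Changes of at least 2-fold numbered 144 with the DESeq2 Wald test (90 falls), for which the cause was not tested, and 362 without a low-count filter (251 falls), where more low genes were tested. They numbered 25 with glmTreat (10 rises, 15 falls), which tests the size itself. Camera with an estimated correlation called 0 lists, with 2 at an unadjusted p under 0.05, where the preset one called 15. Fry called 4, the histone (fry adjusted p = 0.000415), E4F1 target (0.00209), integrated stress response (0.00209) and cholesterol synthesis lists (0.00703). With the cell cycle score as a covariate 972 genes changed (579 up, 393 down), 98 by at least 2-fold (46 falls), and 6 lists were called. The covariate follows the groups and widens the standard errors, so part of this loss follows from its construction.

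Leaving out 1 library gave 3031 to 5370 changed genes (1605 to 2833 rises, 1419 to 2537 falls), 175 to 425 of at least 2-fold (69 to 151 rises, 106 to 274 falls) and 10 to 15 lists. The values of 425, 151 and 274 were without control library 2, 3031 without E4F1 shRNA library 2, and the falls were 1503, 1419 and 1426 without control library 3, E4F1 shRNA library 1 and E4F1 shRNA library 2. Fewer samples may lower the counts, but these runs all had the same number of libraries and still differed. The cause of the lower and of the higher counts was not tested.

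Results that turned direction had not passed the test unless said here, and the cause was not tested. LYZ was 0.87 with limma-voom. VWF was 0.088 with the GC-content offset, 0.096 with block and offset, and 0.019 ignoring strand, where TEK was 0.016 and MT-ND5, called in the report, 0.053. MT-ND6 lies on the opposite strand beside MT-ND5. For lists a turn is of the test's direction: pyruvate entry was −0.024 without filter, −0.036 with the block and −0.036 on ranks. Mitochondrial ribosomal proteins were −0.011 with the stricter filter, −0.0030 with the GC-content offset, −0.0031 with block and offset, −0.0082 in fry and −0.074 with the covariate. The PIKK list was −0.062 in fry and −0.10 with the covariate, and the osteoblast list −0.011 and 0.081. With the covariate BMP4 was −0.092, SPP1 0.12 (both called in the edgeR test), TEK 0.22, the called p53 list 0.016 and mitosis list −0.011, packaging line genes −0.031 and blood genes −0.84. Leaving out 1 library gave VWF −0.25 to 0.18, TEK −0.096 to 0.12, CD74 −1.04 to 0.81, LYZ −0.79 to 2.33, PTPRC −0.33 to 0.061, DLD −0.090 to 0.023, mitochondrial ribosomal proteins −0.020 to 0.027, pyruvate entry −0.053 to −0.0025, the PIKK list −0.092 to −0.027 and the osteoblast list −0.043 to 0.027.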

Other observations

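The tests of neighbouring genes, of the octamer in E4F1 itself, of parts of a gene set split by expression, of the stress response list against the bound of 0.5 and with the cell cycle score as a covariate were chosen after the results were seen, as were the cardiolipin, diphthamide, uniporter and p53 pathway genes named here and DNASE1L2. Besides CRLS1, a second enzyme of the cardiolipin pathway fell: TAFAZZIN, which remodels cardiolipin in mitochondria, went from 11.5 ± 1.98 to 0.836 ± 0.173 CPM (n = 3 each, log2 −3.77, edgeR adjusted p = 9.62e-10). The phosphatidylglycerophosphate synthase gene PGS1 fell by 0.32 on the log2 scale (edgeR adjusted p = 0.00247), while CDS1 rose and TAMM41 (log2 −0.15, edgeR adjusted p = 0.345) and PTPMT1 (log2 0.22, 0.0999) did not pass the test. In the diphthamide pathway DPH5 fell 10.3-fold, DPH1 (log2 −0.54) and DPH2 (log2 −0.21) fell, DPH6 rose (log2 0.63), and DPH3 (0.13), DPH7 (0.02) and DNAJC24 (−0.07) did not pass.

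Around the mitochondrial calcium uniporter, MCU rose together with its regulator gene MCUR1 (log2 0.61, edgeR adjusted p = 1.44e-06) and the related pore gene MCUB (log2 0.47, edgeR adjusted p = 0.00207), while MICU2 (0.10) and SMDT1 (−0.11) did not pass. Among p53 targets, MDM2 had log2 −0.13 (edgeR adjusted p = 0.222), and CDKN1A fell by 0.38 (0.00603) with overlap between the groups. DNASE1L2, which starts 74 bases downstream of E4F1 on the same strand, went from 0.880 ± 0.0684 to 0.143 ± 0.0936 CPM, the latter mean lying under the floor of 3 reads per library.

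Cell cycle lists were higher, and p53 and lysosome lists lower, along a line on which the control libraries also differed among themselves. Over the 202 genes of these 5 lists, control 2 minus control 3 had r = 0.825 (0.773 to 0.871, bootstrap over genes, which are not independent replicates) with the E4F1 shRNA libraries minus control 1, the other 2 pairs of controls had r = 0.429 (1 minus 3, against control 2) and 0.767 (2 minus 1, against control 3), and the first comparison had r = 0.382 over all 15765 genes, so a state of the culture that varies between pools may account for part of this pattern. GC content as the cause is argued against by the GC-content offset, with which the lists kept 90.8% of their mean and all 5 stayed called. The genes of the stress response list also followed that line in order (r = 0.729, 0.708 and 0.192 in the same 3 comparisons), so a part of their rise along it stays open, but the ratio of their median on it to their change was 0.247 (0.154 to 0.416), below the bound of 0.5 but not wholly below the 0.25 set in advance, and it stayed called with the cell cycle score as a covariate (mean 0.45), which argues against the line as its whole cause. A biological effect of E4F1 depletion on the cell cycle stays open, because a state that differs by pool and one that follows the knockdown cannot be separated with 3 pools per group.

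Genes with CTTATCT in the 3' UTR were higher in the E4F1 shRNA libraries (t = 18.6, against at most 4.60 in 100 permutations, p = 0.0099, the smallest these can give), and a candidate explanation is repression of these genes in the control libraries by a seed match of the scramble shRNA, whose sequence is not given in the sources used here. Genes with more than 1 copy lay 0.0379 (SE 0.0212) above genes with 1, too close to decide, and 25 of 65 genes that rose at least 2-fold held the heptamer (38.5%, against 10.3% of other genes, odds ratio 5.47, 3.17 to 9.27), under the majority set in advance, with 13 of 21 (61.9%) among those with average log2 CPM of at least 3 and 6 of 30 (20%, against 6.87%) among those under 2, an excess that partly restates how the heptamer was picked, as the highest of a scan of the same fold changes. Genes with the extension CTTATCTA had a shift of 0.232 (SE 0.0173, 244 genes), against 0.142 for CTTATCT without it. No bound had been set in advance for this extension. A base composition or DNA element working on both strands is argued against by the reverse complement AGATAAG, whose shift was −0.0680 times that of CTTATCT. The line among controls also moved these genes (t = 6.005 in control 2 minus control 3, past the 4 set in advance for it). By that rule the line counts as a possible cause. With the cell cycle score as a covariate 81.1% of the shift stayed (t = 16.9). This argues against the line as the whole cause, a reading not set in advance, and the score is not that line itself. A changed cellular microRNA with this seed stays open and untested. Of the stress response list 3 of 29 members held the heptamer, and of the replication, mitosis and recombination lists 13 of 124. Members without it kept 90.1% and 98.6% of the means of these lists. That argues against a match in the members' own 3' UTRs as the cause of those rises. An indirect effect through other genes that hold the heptamer was not tested and stays open.

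For the 159 genes that fell at least 2-fold, a seed match of the E4F1 shRNA was looked for among the heptamers scanned. The lowest, TGCTTTA, had a shift of −0.0567 over all genes that hold it, above the −0.1 set in advance. Of 112 falls with a 3' UTR, 21 held it (18.8%, against 18.7% of other genes, odds ratio 1.001, 0.590 to 1.63). This argues against a match to a scanned heptamer as the whole cause. A seed among the less frequent heptamers, which were not scanned, stays open. With 12 of 38 (31.6%, against 20.1%, odds ratio 1.83, 0.842 to 3.77) among those with average log2 CPM of at least 3, TGCTTTA stays open for a part of these. The core TGACGT of E4F1 sites in the first 100 transcribed bases was no more frequent in these genes (odds ratio 0.505, 0.181 to 1.14), a search that leaves out sequence upstream of the start. The line among controls had a ratio of 0.307 (0.115 to 0.425) over all of them. Of the 40 with average log2 CPM of at least 3, 80.0% stayed called with the cell cycle score as a covariate (median −1.18 before and −1.23 after), which argues against that line, whereas the 119 lower genes kept 68.6% of their median (−1.24 before, −0.85 after) and 10 stayed called as the median SE went from 0.33 to 0.52, so for them the line and a loss of E4F1 cannot be told apart. For the other better expressed falls a direct or indirect effect of E4F1 depletion is a hypothesis that may be followed up in promoter sequence, which was not analysed here.

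Values of further tests follow, without explanation except for the octamer. Genes with the octamer TTGCTTTA had a shift of −0.092 on the log2 scale, which differed by −0.0520 (SE 0.0102) from genes with only a part of it. The difference was −5.09 SE, past the bound set in advance for a seed match of the E4F1 shRNA. Such a match stays a candidate, as the sequence of that shRNA is not given in the sources used here. The other extension, TGCTTTAA, had −0.045 against −0.064 for TGCTTTA without it. The TGCTTTA shift kept 103% with the cell cycle score as a covariate. Among the listed E4F1 targets, DLAT, PDPR and CHEK1 hold TGCTTTA in the 3' UTR, while TTI2, ELP3, MPC1 and DLD do not. E4F1 itself holds TTGCTTTA once, in its 3' UTR of 170 bases (chromosome 16, 2235713 to 2235720, 30 bases from the transcript's end). With E4F1 counted in both, the octamer stood in 3 of 687 3' UTRs no longer than this (0.437%) and in 4.49% of transcripts of similar length. Neighbours that start within 1000 bases on the opposite strand of a gene that fell at least 2-fold also fell in 7 of 12 cases, against 396 of 3146 for other genes (odds ratio 9.71, 2.64 to 39.0, Fisher's exact test, two-sided, p = 0.000233), with DPH5 and its divergent transcript DPH5-DT counted both ways. Without overlapping neighbours this was 2 of 3 (odds ratio 13.9, 0.719 to 821). The next gene downstream on the same strand rose with an odds ratio of 1.26 (0.478 to 2.84). Of 17 myeloid markers detected, 5 (29.4%, 10.3% to 56.0%, Clopper-Pearson) were highest in control library 2. Without that library 3.77% of the 159 falls lost their call, and all 5 lists of the cell cycle line kept theirs.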
